A study of Cricetulus griseus with 4 samples.

How the data were processed

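Poly(A) RNA was sequenced from CHO-K1, an established Chinese hamster ovary cell line. Per the labels' protocols, cells were plated in 6-well plates for 24 hr and then kept for another 24 hr with DMSO, with a compound selective for VDR activation, with one selective for SREBP inhibition, or with 25-hydroxyvitamin D3. The treatment medium held 5% lipid-depleted serum, 50 µM compactin (a statin) and 50 µM mevalonate. Total RNA was isolated with ISOGEN and libraries were made with a TruSeq Standard mRNA kit, per the labels' protocols. Each treatment has 1 library, and the labels used here give no dose, structure or code name for the compounds.

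The authors deposited estimated counts per gene, which need not be whole numbers, and 15.8 to 16.8% of the rows in each library were not whole. The deposited table also holds the authors' FPKM values, counts scaled by gene length and a library total. The ratio of count to FPKM between libraries was constant over genes with more than 100 counts in each library, within 0.00178%. The implied FPKM library totals, relative to DMSO, were 0.994 for 25-hydroxyvitamin D3, 1.05 for the SREBP inhibitor and 1.10 for the VDR activator, against 0.999, 1.09 and 1.11 for the summed counts. The submitters' processing notes name bcl2fastq (version 1) and TopHat2 (version 2), with no role or order. The counting tool, genome build and annotation version are not given in the sources used here, so no coordinates are reported. No column belonged to an unlisted sample.

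The table has 21266 rows, each marked as a protein gene, of which 5932 carry only a LOC identifier in place of a symbol. Gene identifiers of 19611 rows were found in a RefSeq gene table of assembly CriGri-PICRH-1.0, which was used only for names. Rows of 1 gene on several loci were summed, which joined the rows of 479 genes and left 20754 genes. For 20 members of the gene lists that stand under a LOC identifier, the row was found from its description or gene identifier. Members whose row could not be told from a close relative, such as Scd2 and Ctsl, were left out.

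Estimated counts were rounded to whole numbers. Library sizes were adjusted with the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, and values are CPM, the counts of a gene per 1000000 of the effective library size. The TMM factors were 1.02 for DMSO, 0.955 for 25-hydroxyvitamin D3, 0.997 for the SREBP inhibitor and 1.03 for the VDR activator. One CPM corresponded to 21.7, 20.4, 23.2 and 24.4 counts in these libraries, in the same order. Differences are on the log2(CPM + 1) scale, which understates the change of genes near 1 CPM, and folds of named genes are ratios of CPM.

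With 1 library per group no test across conditions was possible, no p-value is given and no difference has a replicate check. A gene was called 2-fold higher or lower when log2(CPM + 1) differed by 1 or more, with at least 1 CPM and 10 counts in at least 1 of the 2 libraries. Where a 95% interval is printed beside the fold of a named gene, it comes from the exact Clopper-Pearson interval of the gene's counts in the 2 libraries. These intervals cover counting error only, and they compare libraries, not conditions. They treat reads as independent, which reads without molecular identifiers need not be, so they can be too narrow even for counting error. The rule was tested on simulated Poisson counts of all 20754 genes drawn from the mean of each pair of libraries. Counting error alone gave 0 calls in either direction in each of the 6 comparisons. The rule leaves little room for such calls, and this does not tell how many would arise between replicate cultures. Of 100 genes changed 3-fold, 97% were recovered for 25-hydroxyvitamin D3 against DMSO, 99% for the SREBP inhibitor against DMSO and 94% for the VDR activator against DMSO. For the comparisons between treatments the shares were 92% for 25-hydroxyvitamin D3 against the SREBP inhibitor, 98% against the VDR activator, and 95% for the SREBP inhibitor against the VDR activator.

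The 21 gene lists were fixed before the data were examined, as were the rules of size, the comparisons and the alternatives except where stated. They cover cholesterol synthesis enzymes, cholesterol uptake and SREBP feedback, fatty acid and NADPH synthesis, vitamin D receptor targets, vitamin D metabolism and receptor partners, LXR targets, ER stress chaperones and ERAD, the integrated stress response, NRF2 targets and p53 targets. The others cover cell division, DNA replication, hypoxia and glycolysis, interferon and inflammatory genes, extracellular matrix and mesenchymal genes, lysosome and autophagy, lipid droplets and fatty acid oxidation, immediate early genes, ribosomal proteins, widely expressed reference genes and markers of other lineages. Another 11 lists were chosen after the data were seen and appear only in the closing section, except the mitochondrial-encoded mRNAs, which the report also gives. The median difference of a list was placed as a percentile among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. This describes these libraries and is not a test, since members of a list are not independent of each other. Over the 21 lists and 6 comparisons, 58 of 126 medians lay outside the middle 95% of random lists.

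The named genes follow a rule fixed in advance. Vdr, Cyp24a1, Srebf1, Srebf2, Insig1 and Fasn were always taken, with 2 genes that are not reported here. The 6 most higher and 6 most lower genes with a symbol and at least 5 CPM were added for each treatment against DMSO, and 4 each way between treatments. From each list, up to 4 members with the largest differences past the 2-fold limit were added for the treatments against DMSO. The rule took 82 genes for 25-hydroxyvitamin D3, 43 for the SREBP inhibitor and 29 for the VDR activator against DMSO, of which the text gives a part. The mitochondrial-encoded genes, and the genes Yars, Gars, Slc1a5, Mthfd2 and Cct4 of the added lists in the closing section, were chosen after their values were seen, although ATP6 was also taken by the rule in 25-hydroxyvitamin D3 against the SREBP inhibitor.

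To set differences side by side without a shared library, the 4 libraries were split into pairs. The SREBP arm sets the SREBP inhibitor minus DMSO against 25-hydroxyvitamin D3 minus the VDR activator, and the VDR arm sets the VDR activator minus DMSO against 25-hydroxyvitamin D3 minus the SREBP inhibitor. The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a minimum of 5 CPM, a 1.5-fold limit, median-of-ratios scaling and scaling to the same total count. Added after the data were seen were TMM without the 13 mitochondrial-encoded genes, the library totals of the authors' FPKM, and rows as deposited without summing. Figures were drawn with matplotlib 3.10.9.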

Results

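The series addresses which parts of the activity of 25-hydroxyvitamin D3 go with each of its known targets in CHO-K1 cells. This main circulating form of vitamin D acts on the vitamin D receptor (VDR) and also lowers the activity of the sterol regulatory element-binding proteins (SREBPs), the transcription factors that drive cholesterol and fatty acid synthesis. A selective SREBP inhibitor and a selective VDR activator stand for the separate activities. RNA was sequenced from 4 cultures treated for 24 hr, 1 library each, in sterol-depleted medium with compactin, which is known to raise SREBP activity. Total counts were 21353306 for DMSO, 21335639 for 25-hydroxyvitamin D3, 23286707 for the SREBP inhibitor and 23653321 for the VDR activator, and 11917, 11426, 11792 and 11918 genes had at least 10 counts. Mitochondrial-encoded mRNAs made up 6.81% of the counts in DMSO (95% Clopper-Pearson interval 6.80 to 6.82), 5.25% with the SREBP inhibitor (5.24 to 5.26) and 5.93% with the VDR activator (5.92 to 5.94), but 0.753% with 25-hydroxyvitamin D3 (0.750 to 0.757). There are no replicates, so every difference is between these libraries, and intervals cover counting error only. The doses of the compounds are not in the labels, so sizes of response are set side by side without a matched dose.

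The best-known target gene of each activity separated the libraries. Cyp24a1, the vitamin D 24-hydroxylase and a classical VDR target, stood at 3.27 CPM in DMSO, 5.99 with the SREBP inhibitor, 185 with 25-hydroxyvitamin D3 and 258 with the VDR activator. It was 56.5-fold above DMSO with 25-hydroxyvitamin D3 (95% interval 44.7 to 72.5), 79.0-fold with the VDR activator (62.5 to 101) and 1.83-fold with the SREBP inhibitor (1.37 to 2.47). Vdr itself was at 48.0 CPM in DMSO and between 37.4 and 42.6 in the treated libraries. Insig1, an SREBP target that holds SREBP in the endoplasmic reticulum, was at 452 CPM in DMSO and 410 with the VDR activator, but at 118 with the SREBP inhibitor and 61.9 with 25-hydroxyvitamin D3. Hmgcs1, the HMG-CoA synthase of the mevalonate pathway, went in the same order, with 2147, 1941, 404 and 118 CPM. Of 21 cholesterol synthesis enzymes, 20 were lowest with 25-hydroxyvitamin D3, next with the SREBP inhibitor and higher in DMSO.

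**Figure D1:**
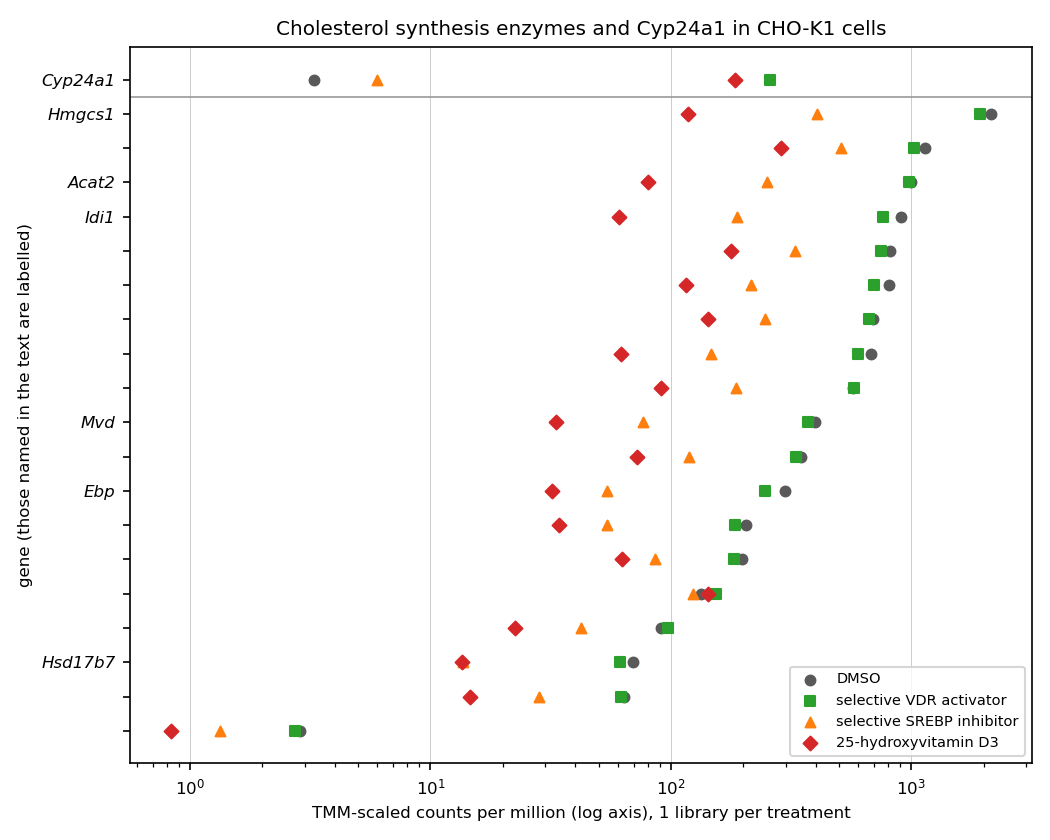
CPM of 19 of the 21 cholesterol synthesis enzymes and Cyp24a1 (vertical axis) in the 4 libraries on a log axis, 1 point per library, with the genes named in the text labelled. For 18 of these 19 enzymes 25-hydroxyvitamin D3 lies lowest and the SREBP inhibitor between it and DMSO, while Cyp24a1 lies at 185 and 258 CPM with 25-hydroxyvitamin D3 and the VDR activator and at 3.27 CPM in DMSO.

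25-hydroxyvitamin D3 against DMSO gave the widest difference from the control, with 1332 genes at least 2-fold higher and 1403 at least 2-fold lower among 11482, or 23.8%. Of these, 161 were at least 4-fold higher and 279 at least 4-fold lower. A pseudocount of 5 turned the 2-fold balance, with 1019 higher and 830 lower, and so did a minimum of 5 CPM, with 1297 and 1166. Scaling to the same total count moved it the other way, to 1110 higher and 1553 lower, and the FPKM library totals to 1129 and 1543. Lipid synthesis genes were lower as a group. All 21 cholesterol synthesis enzymes were measured, 20 were at least 2-fold lower and 0 higher, and their median difference of -2.27 log2 was below all 10000 random lists. Hmgcs1 was 18.2-fold lower (17.5 to 19.0), the isopentenyl diphosphate isomerase Idi1 14.9-fold (14.1 to 15.8) and the acetyl-CoA acetyltransferase Acat2 12.4-fold. Among 18 measured genes of cholesterol uptake and SREBP feedback, 5 were 2-fold lower and 0 higher, with a median of -0.59, in the 0.07th percentile. They included Insig1 at 7.30-fold (6.88 to 7.75), Lpin1 at 7.16-fold and the sterol carrier gene Stard4 at 4.08-fold. Srebf2 was 1.95-fold lower and Srebf1 1.62-fold lower. Of 20 fatty acid and NADPH synthesis genes, 9 were 2-fold lower and 0 higher (median -0.78, below all random lists), among them the acetyl-CoA synthetase Acss2 at 16.3-fold (14.6 to 18.3), Aacs at 7.93-fold, Elovl6 at 4.58-fold and the fatty acid synthase Fasn at 3.04-fold (2.97 to 3.11).

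Of 40 listed VDR target genes, Cyp24a1 among them, 18 were measured, and these did not move together. Of the 18, 3 were 2-fold higher and 2 lower. Their median was -0.04, in the 42.4th percentile, and so had the opposite sign to Cyp24a1. The other higher members were the drug efflux pump gene Abcb1, at 4.68-fold (4.43 to 4.95), and the growth factor gene Hbegf, at 2.60-fold (2.05 to 3.32), and Pdlim2 was 3.85-fold lower (3.18 to 4.69). Among 14 genes of vitamin D metabolism and receptor partners, Cyp24a1 alone passed 2-fold. LXR targets had a median of -0.91, in the 0.12th percentile, with 4 of 11 lower and 2 higher. The lower ones included Nr1h3, the gene of LXR alpha, at 2.84-fold, and Rab7b at 5.14-fold. The cholesterol efflux transporter gene Abca1 was 10.5-fold higher (9.91 to 11.1).

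Genes of the integrated stress response, the program run by the transcription factor ATF4, were higher with 25-hydroxyvitamin D3. Of 19 measured, 17 were at least 2-fold higher and 1 lower, and the median of 2.46 was above all random lists. Atf3 was 37.2-fold higher (25.6 to 56.3), Chac1, which degrades glutathione, 15.9-fold (12.4 to 20.7), the amino acid transporter subunit Slc3a2 13.1-fold (12.4 to 13.8) and Ddit3, which encodes CHOP, 12.3-fold (10.6 to 14.3). ER chaperones and ERAD genes did not share this difference, with 1 of 20 higher (Herpud1, at 3.23-fold), 0 lower and a median of -0.22. NRF2 targets, which share Slc7a11 with the integrated stress response list, went both ways. Among 18, 6 were higher, including the heme oxygenase gene Hmox1 at 37.5-fold (35.3 to 39.9; 49.1 against 1843 CPM), Slc7a11 at 8.86-fold and Txnrd1 at 4.35-fold, while Nqo1 was 5.59-fold lower (4.94 to 6.33).

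Cell cycle genes were higher. Of 21 cell division genes 12 were 2-fold higher and 0 lower (median 1.12), led by Cdc20 at 4.98-fold (4.62 to 5.37), Cenpa at 3.43-fold and Ube2c at 2.68-fold. Of 22 DNA replication genes 11 were higher and 1 lower (median 1.01), led by Ccne1 at 4.87-fold (3.92 to 6.10), Cdt1 at 3.77-fold and Mcm7 at 3.53-fold. Both medians were above all random lists. Ribosomal protein genes had a median of 0.65, in the 99.86th percentile, although only Rps2 of 24 passed 2-fold, at 2.34-fold. Among 17 immediate early genes 4 were higher and 6 lower. Myc was 8.45-fold higher (7.65 to 9.35) and Fosl1 8.20-fold, while Egr1 was 11.8-fold lower (9.72 to 14.5) and Dusp6 8.48-fold. In the same library all 13 mitochondrial-encoded genes, named after their values were seen, were between 5.71-fold lower (COX1, 5.67 to 5.76) and 18.7-fold lower (ATP8, 16.5 to 21.3).

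Extracellular matrix and mesenchymal genes had a median of -0.92, in the 0.05th percentile, with 6 of 14 at least 2-fold lower and 1 higher. The connective tissue growth factor gene Ctgf was 144-fold lower (83.9 to 271; 91.7 against 0.638 CPM), the collagen gene Col3a1 9.95-fold (9.49 to 10.4) and Postn 5.26-fold, but Cyr61, of the same family as Ctgf, was 9.62-fold higher (8.36 to 11.1). Of 17 lipid droplet and fatty acid oxidation genes, 5 were lower and 2 higher (median -0.42, 1.81th percentile). The lipid droplet gene Plin4 was 8.87-fold lower, and the lipid droplet coat gene Plin2 was 3.50-fold higher (3.40 to 3.60). Among 11 interferon and inflammatory genes 4 were higher and 2 lower (median -0.14), led by Ptgs2, which encodes COX-2, at 12.7-fold (9.81 against 124 CPM), and Cxcl1 at 6.15-fold. Hypoxia and glycolysis genes had 6 of 19 higher and 2 lower (median 0.50), with Pdk1 at 3.80-fold and Vegfa at 3.69-fold. Of 16 p53 targets 3 were higher and 5 lower (median -0.20), with Plk2 6.39-fold higher and Tp53inp1 10.3-fold lower. Of the 18 lysosome and autophagy genes Mitf alone was higher, at 2.20-fold (median -0.07). Among 20 widely expressed reference genes 4 were higher and 0 lower (median 0.21), Actg1 most at 2.87-fold, and of 21 markers of other lineages only 3 were measured (median -0.60), with Tek 5.36-fold lower (2.38 to 14.2) at 1.84 CPM in DMSO. Outside the lists, 2 genes had the largest differences among genes with a symbol and at least 5 CPM. These were the chemokine gene Cxcl3, 368-fold higher (226 to 643; 0.737 against 271 CPM), and the water channel gene Aqp1, 192-fold lower (92.9 to 478; 65.9 against 0.343 CPM). Abhd6, a monoacylglycerol hydrolase, and the secreted glycoprotein gene Stc2 were 70.9-fold and 50.1-fold higher.

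The selective SREBP inhibitor against DMSO gave 223 genes at least 2-fold higher and 160 lower among 11449, or 3.35%. With a pseudocount of 0.1 more genes were lower, 307 against 274 higher. Sterol synthesis was again lower as a group, with 19 of 21 cholesterol synthesis enzymes at least 2-fold lower, 0 higher and a median of -1.61, below all random lists. The lowest were Ebp at 5.52-fold (5.20 to 5.87), Hmgcs1 at 5.32-fold (5.20 to 5.44), Mvd at 5.20-fold (4.94 to 5.47) and Hsd17b7 at 5.09-fold. Of 18 uptake and feedback genes 5 were lower (median -0.17, 0.68th percentile), including Insig1 at 3.84-fold (3.68 to 4.01) and Lpin1 at 3.04-fold. Of 20 fatty acid genes 6 were lower (median -0.52, below all random lists), led by Acss2 at 6.18-fold (5.77 to 6.62) and Aacs at 3.64-fold, while Fasn was 1.98-fold lower (1.95 to 2.02), just short of the limit. Srebf2 was 1.67-fold lower, and Srebf1 was at 14.8 against 16.2 CPM, a ratio whose interval included 1. None of the 18 measured VDR targets and none of the 14 genes of vitamin D metabolism and receptor partners passed 2-fold, with medians of -0.04 and -0.03.

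Integrated stress response genes were higher in this library too, with 16 of 19 at least 2-fold higher, 1 lower and a median of 1.79, above all random lists. Ddit3 was 7.46-fold higher (6.42 to 8.70), Atf5 6.49-fold (5.87 to 7.17), Slc3a2 5.49-fold (5.19 to 5.82) and the asparagine synthetase gene Asns 4.49-fold (4.09 to 4.94). No gene among 20 ER chaperone and ERAD genes passed 2-fold (median -0.13, 1.20th percentile). Abca1 was 9.76-fold higher (9.23 to 10.3) and the lipoprotein lipase gene Lpl 3.15-fold (3.05 to 3.24), the 2 LXR targets of 11 to pass the limit (median 0.02). Plin2 was 2.40-fold higher, the only one of 17 lipid droplet and fatty acid oxidation genes to do so (median -0.23, 0.43th percentile). Of 18 NRF2 targets 2 were higher, Slc7a11, also in the integrated stress response list, at 3.30-fold and Hmox1 at 3.17-fold (median 0.21). Of 16 p53 targets 1 was higher, Sesn2, at 2.91-fold (median -0.003).

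Cell division genes showed no 2-fold difference with the SREBP inhibitor (median 0.13, 83.4th percentile), and of 22 DNA replication genes Ccne1 was higher at 2.59-fold and Mcm7 at 2.16-fold (median 0.32, 99.96th percentile). Ribosomal protein genes had a median of 0.48, above all random lists, with 0 of 24 past 2-fold. Of 17 immediate early genes Myc and Fosl1 were higher, at 4.11-fold (3.71 to 4.57) and 3.90-fold, and Nr4a1 and Dusp6 lower, at 2.89-fold and 2.18-fold (median -0.37, 0.03th percentile). Among 14 matrix genes Ctgf was 2.85-fold lower (2.62 to 3.10), Col3a1 2.35-fold lower and Cyr61 2.32-fold higher (median -0.17). Hypoxia and glycolysis genes had Pdk1 2.06-fold higher and Ndrg1 2.04-fold lower (median 0.26, 98.6th percentile), and the interferon and inflammatory list had Ccl2 2.14-fold lower (median -0.09). The lysosome list (median 0.05), reference genes (median 0.14) and 3 measured lineage markers (median -0.50) held no gene past 2-fold. Outside the lists, Stc2 was 15.3-fold higher (11.9 to 19.9), the cell adhesion gene Tenm4 17.8-fold (10.8 to 31.6; 0.737 against 13.1 CPM), and Aqp1 lay at 7.32 against 65.9 CPM (7.67-fold to 10.6-fold lower).

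The selective VDR activator against DMSO gave the narrowest difference, with 21 genes at least 2-fold higher and 37 lower among 11431, or 0.507%. With a pseudocount of 5 these were 5 and 14, and with one of 0.1 they were 45 and 86. With a 1.5-fold limit more genes were higher, 279 against 219 lower. Next to Cyp24a1, the largest higher gene with a symbol and at least 5 CPM was the transcriptional coregulator gene Cited1, at 4.45-fold (4.11 to 4.84; 32.3 against 144 CPM). The heparan sulfatase gene Sulf2 followed at 3.05-fold (2.82 to 3.30). Aqp1 was 6.06-fold lower (5.31 to 6.93), Ctgf 4.55-fold (4.12 to 5.03), the laminin gene Lama3 4.13-fold (3.46 to 4.95), Arnt2 2.95-fold, Unc5b 2.68-fold and the chemokine scavenger receptor gene Ackr3 2.61-fold (2.30 to 2.97). Cyp24a1 was the only one of 18 measured VDR targets past 2-fold, and the list's median of -0.12, in the 1.45th percentile, had the opposite sign. It was also the only one of the 14 genes of vitamin D metabolism and receptor partners to do so (median 0.003).

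No gene of the lipid synthesis lists passed 2-fold with the VDR activator. The median of the 21 cholesterol synthesis enzymes was -0.10, in the 3.79th percentile, and 18 of the 21 were slightly lower. Insig1 was 1.10-fold lower (1.07 to 1.13), and Fasn was 1.02-fold higher (1.01 to 1.04). The uptake and feedback list had a median of -0.04 and the fatty acid list one of -0.10, in the 1.90th percentile. The fatty acid list, the integrated stress response and cell division genes had no gene past 2-fold but a median outside the middle 95% of random lists. So did ER chaperones (-0.15, 0.13th percentile), LXR targets (-0.22, 0.17th), lysosome genes (-0.15, 0.20th), p53 targets (-0.16, 0.24th), hypoxia and glycolysis genes (0.14, 97.95th) and ribosomal proteins (0.20, 99.99th). NRF2 targets (0.09), reference genes (0.09) and the 3 lineage markers (-0.39) had no gene past 2-fold and a median inside that range. The integrated stress response had a median of 0.15, in the 99.0th percentile, with 0 of 19 past the limit.

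Cell cycle genes were higher with the VDR activator by less than 2-fold in most members. The 21 cell division genes had a median of 0.66 with 0 past the limit, and the 22 DNA replication genes a median of 0.69 with 3 past it, both above all random lists. The replication licensing factor gene Cdt1 was 2.56-fold higher (2.09 to 3.16), the thymidine kinase gene Tk1 2.08-fold (1.83 to 2.37), Mcm5 2.02-fold (1.89 to 2.17) and, outside the lists, the helicase gene Recql4 2.48-fold. Matrix genes were lower, with a median of -0.53, below all random lists, and Ctgf, Thbs1 (2.43-fold, 2.35 to 2.52) and Postn (2.38-fold) past the limit. Of the immediate early genes Junb and Myc were 2.30-fold and 2.08-fold higher and Nr4a1 2.65-fold lower (median 0.08). In the interferon and inflammatory list Ccl2 was 4.22-fold lower (3.40 to 5.27) and Cxcl1 2.35-fold higher (median 0.02), and of the lipid droplet and fatty acid oxidation genes Cd36 was 2.22-fold lower (median -0.07).

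**Figure D2:**
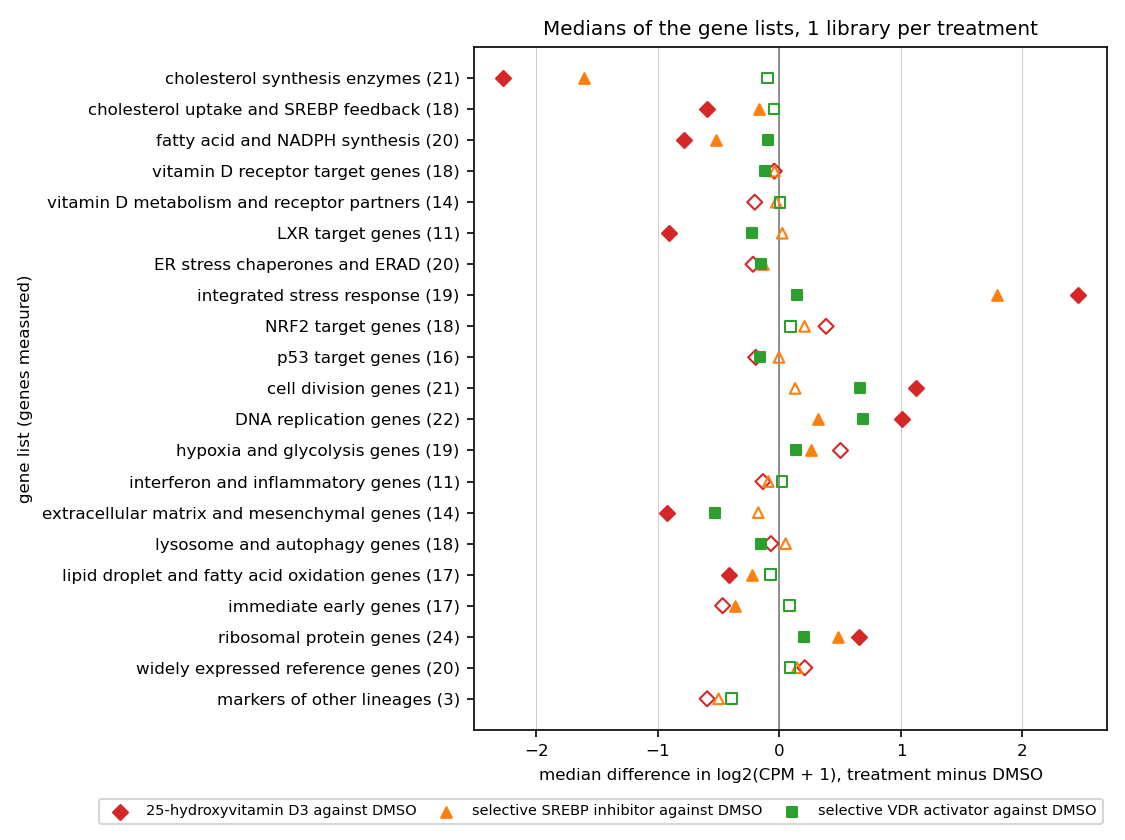
Median difference in log2(CPM + 1) of each of the 21 gene lists against DMSO, with the number of genes measured, 1 library per treatment. Filled points lie outside the middle 95% of 10000 random lists, and the cholesterol synthesis list lies at -2.27 with 25-hydroxyvitamin D3, -1.61 with the SREBP inhibitor and -0.10 with the VDR activator.

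Set directly against the SREBP inhibitor, 25-hydroxyvitamin D3 had 356 genes at least 2-fold higher and 685 lower among 11314, but 237 and 314 with a pseudocount of 5. The cholesterol synthesis enzymes were lower by a further median of -0.88, with 7 of 21 past 2-fold, and Insig1 was 1.90-fold lower (1.78 to 2.03). Cyp24a1 was 30.9-fold higher (26.1 to 36.8). The integrated stress response was higher by a median of 0.85, with 8 of 19 past 2-fold and 1 lower, and cell division genes by 1.01, with 11 of 21 past it. Matrix genes were lower by a median of -0.80. Large single differences were Cxcl3 at 64.8-fold higher, the natriuretic peptide gene Nppb at 26.7-fold, Hmox1 at 11.8-fold and Ptgs2 at 9.70-fold, and Ctgf at 50.5-fold lower, Pcp4l1 at 37.6-fold and the mitochondrial ATP6 at 12.7-fold. Higher genes made up 34.2% of the 2-fold differences, and 21.6% with the library totals of the authors' FPKM, under which the median of all genes moved by -0.11 log2.

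Against the VDR activator, 25-hydroxyvitamin D3 had 973 genes at least 2-fold higher and 1127 lower among 11387, but 738 and 616 with a pseudocount of 5. Cyp24a1 was 1.40-fold lower (1.34 to 1.46) with 25-hydroxyvitamin D3. The cholesterol synthesis median was -2.21 with 20 of 21 enzymes 2-fold lower, Hmgcs1 was 16.5-fold lower (15.8 to 17.2) and Fasn 3.11-fold (3.05 to 3.18). The integrated stress response was higher by a median of 2.20, with 16 of 19 at least 2-fold higher and 1 lower, whereas cell division genes differed by 0.49 with 1 of 21 past it. Cxcl3 was 201-fold higher, Tenm4 164-fold, Abhd6 139-fold and Hmox1 28.5-fold, and Pcp4l1 was 75.9-fold lower, Angpt4 58.5-fold and Slc43a3 55.9-fold. Tenm4 lay below 1 CPM with the VDR activator, so the size of its ratio rests on few reads. Other ratios this large can also divide by a low value. Higher genes made up 46.3% of the differences, 35.9% when libraries were scaled to the same total count and 35.0% with the FPKM library totals. The median of all genes moved by -0.11 and -0.12 log2 under these scalings.

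The SREBP inhibitor against the VDR activator gave 110 genes higher and 84 lower among 11374, but 156 and 180 with a pseudocount of 0.1, and 92 and 100 when libraries were scaled to the same total count. Cyp24a1 was 43.1-fold lower with the SREBP inhibitor (36.5 to 51.4) and Cited1 5.71-fold lower, next to Acss2 (4.97-fold), Mvd (4.85-fold) and Hmgcs1 (4.81-fold). Abca1 was 12.9-fold higher (12.1 to 13.7), Tenm4 45.9-fold from a value below 1 CPM with the VDR activator, Abhd6 15.5-fold and Ddit3 7.09-fold (6.17 to 8.17). The cholesterol synthesis median was -1.62 with 18 of 21 enzymes past 2-fold, the integrated stress response median 1.64 with 14 of 19 higher and 1 lower, and the cell division median -0.55 with 0 of 21 past 2-fold.

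Differences were then set side by side over 11547 genes with no library in common. In the SREBP arm, the SREBP inhibitor minus DMSO and 25-hydroxyvitamin D3 minus the VDR activator correlated across genes with Pearson's r of 0.767 and Spearman's rho of 0.748, and 78.5% of genes had the same sign. Of the 223 genes 2-fold higher with the SREBP inhibitor, 197 were also among the 973 higher in the second difference, where independent lists would share 18.8. Of the 160 lower genes 135 were among the 1127 lower, where independent lists would share 15.6, and 1 gene went in opposite directions. In the VDR arm, the VDR activator minus DMSO and 25-hydroxyvitamin D3 minus the SREBP inhibitor correlated with r of 0.442 and rho of 0.423, and 65.3% of genes had the same sign. Of the 21 higher genes 8 were shared with 356 (0.647 if independent), of the 37 lower genes 29 were shared with 685 (2.19 if independent), and 2 went in opposite directions. Genes are not independent replicates, and these values describe 4 libraries. Both arms are made from the same 4 libraries, so they are not separate evidence. The second difference of the VDR arm does not isolate VDR activity. In it cholesterol synthesis enzymes were still lower (median -0.88) and integrated stress response genes higher (median 0.85).

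**Figure D3:**
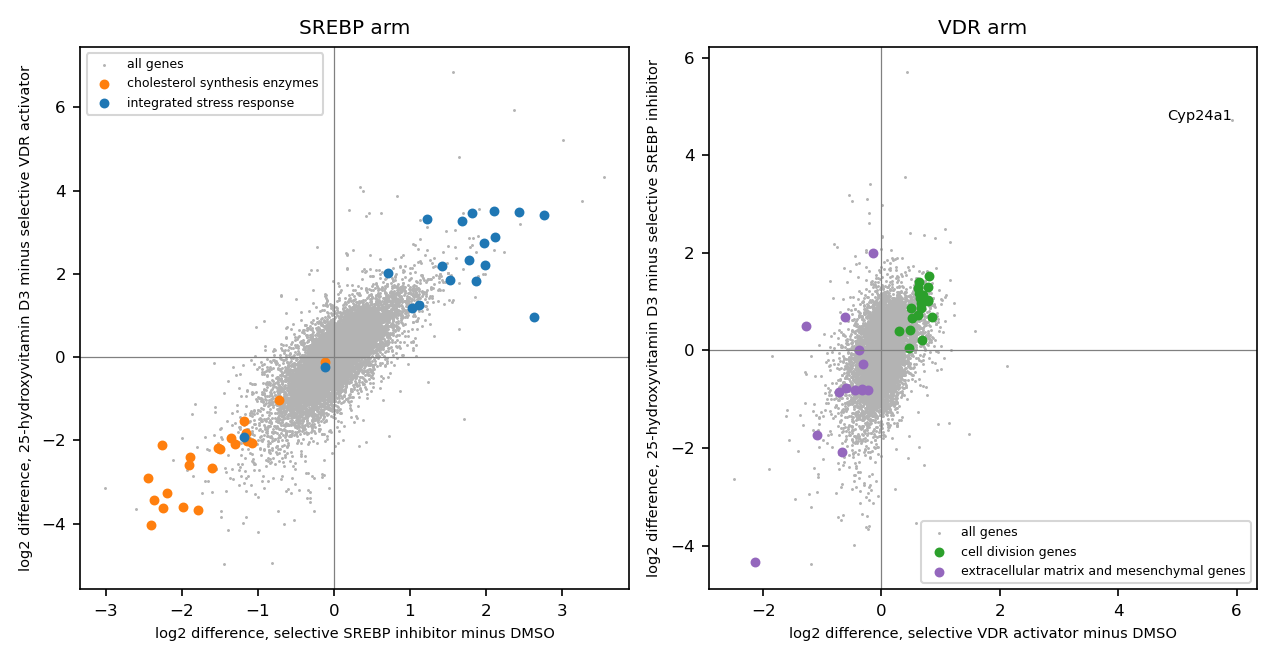
Differences in log2(CPM + 1) of 11547 genes for pairs of comparisons with no library in common, 1 point per gene. In the SREBP arm (left, r of 0.767) cholesterol synthesis enzymes lie mostly low on both axes and integrated stress response genes mostly high. In the VDR arm (right, r of 0.442) all 21 cell division genes lie above 0 on both axes and Cyp24a1 farthest to the right.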

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

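No paired analysis was possible because each treatment has 1 library and no count comes from a test. TMM without the mitochondrial-encoded genes, the FPKM library totals and unsummed rows were chosen after the data were seen. A 1.5-fold limit gave 2773 genes higher and 2709 lower for 25-hydroxyvitamin D3 against DMSO, 908 and 710 for the SREBP inhibitor, 279 and 219 for the VDR activator, 1564 and 1823 for 25-hydroxyvitamin D3 against the SREBP inhibitor, 2331 and 2401 against the VDR activator, and 573 and 502 for the SREBP inhibitor against the VDR activator. A pseudocount of 5 gave 1019 higher and 830 lower for 25-hydroxyvitamin D3 against DMSO, 143 higher and 93 lower for the SREBP inhibitor, 5 and 14 for the VDR activator, 237 and 314 for 25-hydroxyvitamin D3 against the SREBP inhibitor, 738 and 616 against the VDR activator, and 71 and 46 for the SREBP inhibitor against the VDR activator. A pseudocount of 0.1 gave 274 higher and 307 lower for the SREBP inhibitor against DMSO, 45 higher and 86 lower for the VDR activator, and 156 and 180 for the SREBP inhibitor against the VDR activator. Which direction held more genes turned in 8 of 60 alternative pairs of counts and in 5 of the 6 comparisons, so it is not taken as a result. The pseudocounts act on genes near 1 CPM by construction. The FPKM library totals gave 233 higher for 25-hydroxyvitamin D3 against the SREBP inhibitor. Of 320 alternative values, 293 stayed within 1.5 times the count, 0.58 log2 of the list median or 0.1 of the correlation. This share is not a measure of stability. Dropping the filter cannot change a 2-fold count, since such a difference already needs 1 CPM. Of the 320 values, 192 were list medians, many of them smaller than the 0.58 limit itself. The medians of the 4 lipid and vitamin D lists moved by at most 0.33 log2, and by at most 0.12 under another scaling. Of 192 medians over all lists and comparisons, 13 changed sign under another scaling, all with a size of 0.0846 or less. Among 1818 alternative values of named genes, 435 lay outside the counting interval of their gene, 0 of those past 2-fold reversed, and 25 of 1350 past 2-fold came to lie under it, 18 of them with the pseudocount of 5. Depth limits genes near the floor: 3 counts correspond to 0.138 CPM in DMSO, 0.147 with 25-hydroxyvitamin D3, 0.129 with the SREBP inhibitor and 0.123 with the VDR activator.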

Other observations

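The lists and the genes named in this paragraph were chosen after the data were seen, and the genes given with folds lie toward the high end of their lists. With 25-hydroxyvitamin D3 against DMSO the lowest member was at -0.40 log2 among synthetase genes and at -0.17 among transporter genes. Genes that load transfer RNAs and bring in amino acids were higher together with the integrated stress response. Of 20 cytosolic aminoacyl-tRNA synthetase genes, 17 were at least 2-fold higher with 25-hydroxyvitamin D3 (median 1.89 log2), 12 with the SREBP inhibitor (1.13) and 0 with the VDR activator (0.20), each against DMSO. Yars was 6.60-fold higher (95% counting interval 6.23 to 6.999), 3.04-fold (2.86 to 3.24) and 1.05-fold (0.977 to 1.13) in these libraries, and Gars 5.81-fold, 2.84-fold and 1.20-fold. Of 10 amino acid transporter genes 6, 6 and 0 were higher (medians 1.98, 1.38 and 0.09), with the glutamine transporter gene Slc1a5 at 11.98-fold (10.5 to 13.7), 4.62-fold (4.03 to 5.31) and 1.51-fold (1.29 to 1.78). Of 7 serine and one-carbon enzyme genes 7, 6 and 0 were higher (medians 2.00, 1.13 and 0.55), with the mitochondrial folate enzyme gene Mthfd2 at 8.57-fold, 3.99-fold and 1.26-fold. Slc7a11, Slc3a2, Slc7a5, Psat1, Phgdh, Shmt2 and Mthfd2 are also members of the integrated stress response list, so the last 2 lists are not independent of it.

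The 8 subunit genes of the CCT chaperonin, which folds actin and tubulin, had medians of 1.60, 0.75 and 0.33 for 25-hydroxyvitamin D3, the SREBP inhibitor and the VDR activator against DMSO, with 8, 0 and 0 past 2-fold. Cct4 was 4.10-fold (3.97 to 4.24), 1.78-fold (1.72 to 1.84) and 1.26-fold (1.21 to 1.31) higher. It lay at the high end with 25-hydroxyvitamin D3, where the 8 genes ran from 1.49 to 2.03 log2. Mitochondrial ribosomal protein genes had medians of 0.63, 0.33 and 0.17 with 19, 3 and 0 of 76 past 2-fold. Cytosolic ribosomal protein genes had medians of 0.52, 0.46 and 0.21 with 2, 0 and 0 of 72 higher and 1 lower with 25-hydroxyvitamin D3, and proteasome subunit genes 0.55, 0.13 and 0.13 with 2, 0 and 0 of 36. Targets of YAP and TEAD went both ways, with 4 higher and 2 lower of 11 with 25-hydroxyvitamin D3 (median 0.43), 1 and 1 with the SREBP inhibitor (0.10) and 0 and 1 with the VDR activator (-0.14). The extreme members of this list, Ctgf and Cyr61, are also in the matrix list, so the lists are not independent. Heat shock genes had 2 higher and 2 lower of 8 with 25-hydroxyvitamin D3 (median -0.19), 1 higher with the SREBP inhibitor (-0.03) and 0 with the VDR activator (0.10).

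Of the tests that follow, the respiratory chain test with its list as used here and all tests of the integrated stress response were chosen after the results they measure were seen. The 13 mitochondrial-encoded genes were 2-fold or more lower with 25-hydroxyvitamin D3 than in each of the other 3 libraries. Their medians were -3.43 against DMSO, -2.98 against the SREBP inhibitor and -3.22 against the VDR activator. Transcript length is argued against, since 527 nuclear genes of the same length range and at 100 CPM or more in DMSO had a median of 0.16. A lower expression of the whole respiratory chain is argued against by 79 measured genes of its nuclear-encoded subunits, whose median was -0.039 with 2 higher, 0 lower and a lowest value of -0.989. An effect of 25-hydroxyvitamin D3 on the mitochondrial transcripts was not tested, and the handling of this single library was not tested either, so both stay open.

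Integrated stress response genes were higher with 25-hydroxyvitamin D3 and with the SREBP inhibitor than in DMSO, at medians of 2.46 and 1.79. An unusual DMSO library is argued against, since the lower of the medians against the VDR activator library was 1.64. ER chaperones, which the unfolded protein response raises, had medians of -0.22 and -0.13. An unfolded protein response was not tested and stays open. A response to lower SREBP activity may underlie the higher stress genes: the 2 libraries with cholesterol synthesis medians below -1 are the 2 with the higher stress genes. No library lowered SREBP activity by another route, so this cannot be told apart from an effect of these compounds on another target.

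The differences of the SREBP arm correlated across genes with r of 0.767 although no library was shared. A trend with gene length is argued against, with r of 0.767 after a spline of length was removed, and a trend with expression level with r of 0.762. Without the members of the 4 lists for cholesterol, fatty acids and the integrated stress response, r was 0.758 over 11469 of 11547 genes. So few genes were removed that r could hardly fall. Other lipid and stress genes stayed in, so a wider lipid or stress response was not tested. A response that the SREBP inhibitor and 25-hydroxyvitamin D3 have in common was not tested and stays open. Batches of culture or library preparation are not in the labels and were not tested.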
